A study of Mus musculus with 26 samples.

How the data were processed

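Bulk RNA sequencing of mouse embryonic forelimb was measured in 26 libraries from embryonic day 13.5, made under 2 strategies for removing Hic1. The conventional series holds 3 wild type, 3 heterozygous and 3 knockout libraries. The conditional series uses a Prrx1-driven Cre recombinase, which acts in limb bud mesenchyme, and holds 5 control, 5 heterozygous and 7 knockout libraries. Per the labels, the conditional controls carry 1 floxed Hic1 allele without Cre, the heterozygotes carry Cre with 1 floxed allele, and the knockouts carry Cre with a floxed allele on both chromosomes. The labels call the conditional controls wild type, so they are named controls here. Per the labels' protocols, forelimbs were homogenised in RNAzol and polyA RNA went into a stranded mRNA library kit. The labels do not state the strand setting used when reads were assigned to genes.

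The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), as the column names and the series text state. Per the submitters' processing notes, bcl2fastq, TopHat2, Bowtie2 and Cufflinks were used with genome build mm10, with no versions, no gene annotation and no low-value filter given. The 2 deposited tables, 1 per strategy, each list 24340 gene symbols, and any scaling between libraries beyond FPKM is not stated. Each table held 1 empty line, which was not used. Dates stood in place of 27 gene symbols of the conditional table, and all 27 were restored from the line of the conventional table with the same transcription start identifier and locus. Chromosome positions and gene types come from the GENCODE M21 annotation of the same build. No counts of reads are given, so the depth of each library is unknown and no counting error can be given for low values. The sum of FPKM per library ran from 410482 to 490248 in the conventional table and from 436559 to 497121 in the conditional table. Between 16785 and 17215 genes were above 0 in the conventional libraries, and between 16677 and 17242 in the conditional libraries.

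Each table was tested on its own with limma 3.58.1 in R 4.3.3. Values were transformed to log2 of FPKM plus a pseudocount of 1, and genes with a mean of at least 1 FPKM over all libraries of a table were tested, 12717 conventional and 12918 conditional. The 3 genotype groups of a strategy shared 1 estimate of the spread (lmFit, contrasts.fit and eBayes with a mean trend), with no replicate block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on this log2(FPKM + 1) scale and understate the change of genes with low FPKM, so group means in FPKM with their SD stand beside them. The p-values measure the spread between these libraries alone, since the labels do not say whether replicates are separate embryos or litters.

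The tests, the 6 comparisons, the gene lists and the rule for which genes are named were fixed before the data were examined. Named genes are Hic1 and, for the knockout against wild type or control, up to 10 called genes per direction by fold change, leaving out sex-linked transcripts and predicted genes. The other comparisons name up to 5 called genes per direction, or the 5 with the smallest p where none was called. From each list up to 4 members with the smallest p could be named. Named outside this rule, after their values were seen, are 2610507I01Rik, a predicted gene, and the conventional fold changes of genes called in the conditional knockout.

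The 36 lists hold 423 gene entries of known sets plus the ribosomal protein genes, of which 80 were found by symbol; 413 of the 423 matched a table symbol, 5 of them by synonym. They cover limb tissues (tendon, myogenic progenitors, contractile muscle, cartilage, hypertrophic cartilage and bone, joint interzone, irregular connective tissue, mesenchymal progenitors, extracellular matrix, limb patterning factors), other cell types (endothelium, mural cells, primitive and definitive erythroid cells, macrophages, Schwann cells, neurons, epidermis), signalling pathways (BMP and TGF-beta, Wnt, Hedgehog, FGF, Notch, retinoic acid), literature targets of HIC1, p53 targets, proliferation, hypoxia and glycolysis, immediate early genes, interferon response, developmental timing, imprinted genes, genes near Hic1, sex-linked transcripts, mitochondrially encoded genes and ribosomal proteins. Each list with at least 3 tested members, other than the sex-linked one, was tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 34 lists of a comparison. Camera was also run with an estimated correlation. The sex-linked list gives values alone, and 0 of the 9 mitochondrially encoded genes matched a table symbol, so none was measured under the names listed.

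The 2 strategies were compared by the overlap of called genes (one-sided Fisher exact test over the 12557 genes tested in both), by the correlation of fold changes across genes, and by a test of the difference of each gene's fold changes, which uses both moderated standard errors. After the data were seen, the genes called in the conditional knockout were also looked up in the conventional knockout as 2 lists, up and down.

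Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries of different genotype, across genes and after removing group means. In the conventional table these correlations ran from 0.349 to 0.678 for knockout with wild type, 0.251 to 0.717 for heterozygote with wild type and 0.244 to 0.652 for knockout with heterozygote, all above the minimum of 0.1 set for pairing. The numbers therefore follow some shared source of spread there, though in each comparison the same number was the best match for 2 of 3 pairs. Fits with a replicate block are given beside the results they change. In the conditional table the lowest was -0.308, so the numbers do not pair. The deposited column names carry letters whose meaning is not stated. In the conventional table replicate 1 of each genotype carries CH (3 libraries) and the other 6 carry CL. A difference between CH and CL alone could therefore correlate same-numbered libraries. Of the conditional libraries 5 carry NZ (2 control, 1 heterozygous, 2 knockout), 1 heterozygous library carries OA, 9 carry OB (1 control, 3 heterozygous, 5 knockout) and 2 control libraries carry OC. Fits with these letters as a batch term were added after the column names were seen, as were fits with each library's slope on transcript length and list tests without conventional knockout replicate 1. Since OC marks controls alone and OA a heterozygote alone, these libraries do not bear on the contrasts once the letters are a term. The control side of the conditional contrasts then rests on the NZ and OB controls.

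The alternatives set in advance were a pseudocount of 0.1, no low-value filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalisation, a replicate block, a fit on the compared groups alone, robust eBayes, array weights, an estimated correlation for lists, and leaving out each library. The usual array-weight method did not converge on the conventional table and gave weights that let 1 library dominate; gene-by-gene weights replaced it in the 3 conventional comparisons after this was seen. Results were set against other splits of the same libraries into groups of the same sizes, all 10 for 3 against 3 and 100 drawn at random otherwise.

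The tests were tried on simulated data with 200 changed genes. For the conventional knockout against wild type, 4.48% of tested genes changed by 0.5 on the log2 scale were recovered, 56.7% at 1 and 89.1% at 2, and 10% of the calls were unchanged genes. For the conditional knockout against control, the shares were 89.6%, 97.0% and 100%, with 4.04% of calls on unchanged genes. With no list changed 0 of 34 lists were called in either simulation, and lowering the extracellular matrix list by 1 gave 1 call, that list. For the test of the difference between strategies the shares were 3.97%, 55.8% and 90.9%. Simulated libraries carried no batches, and each gene was drawn independently, so members of a list were not correlated. The simulated list tests therefore do not show how often lists are called in error in the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.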

Results

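HIC1 is a transcriptional repressor, and the series asks what its loss does to gene expression in the embryonic forelimb under 2 knockout strategies. The 26 libraries fall into 6 groups at E13.5. The conventional groups are wild type (n = 3), heterozygote (n = 3) and knockout (n = 3). The conditional groups are control (n = 5), heterozygote (n = 5) and knockout (n = 7), with Prrx1-driven Cre in the last 2 of these. Values are FPKM as the authors deposited them, and the depth behind them is unknown. Conventional knockout replicate 1 stood apart from the other libraries of its table, with a median correlation of 0.869 against them, where the other libraries with the same column letters (CH) had at least 0.970. Counts of calls without it are given with the conventional knockout comparisons.

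Hic1 itself followed the labels in every group. It lies on chromosome 11 at 75164565 to 75169519 on the minus strand (mm10). In the conventional series it stood at 56.5 ± 7.56 FPKM in wild type (SD, n = 3), 33.5 ± 3.42 in the heterozygote (n = 3) and 1.70 ± 0.748 in the knockout (n = 3), or 59.2% and 3.00% of wild type. In the conditional series it stood at 60.6 ± 5.52 FPKM in the control (n = 5), 31.9 ± 2.52 in the heterozygote (n = 5) and 4.82 ± 1.13 in the knockout (n = 7), or 52.6% and 7.95% of control. The highest knockout library was 6.16 FPKM and the lowest heterozygote library was 28.0 in the conditional series. Hic1 fell by 4.44 ± 0.20 on the log2 scale (SE) in the conventional knockout against wild type, with an adjusted p of 1.20e-04. In the conditional knockout against control it fell by 3.43 ± 0.12, with an adjusted p of 3.58e-12. The labels do not say which part of the gene is removed, so the residual FPKM does not tell intact transcript from transcript of the part left in place.

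**Figure D1:**
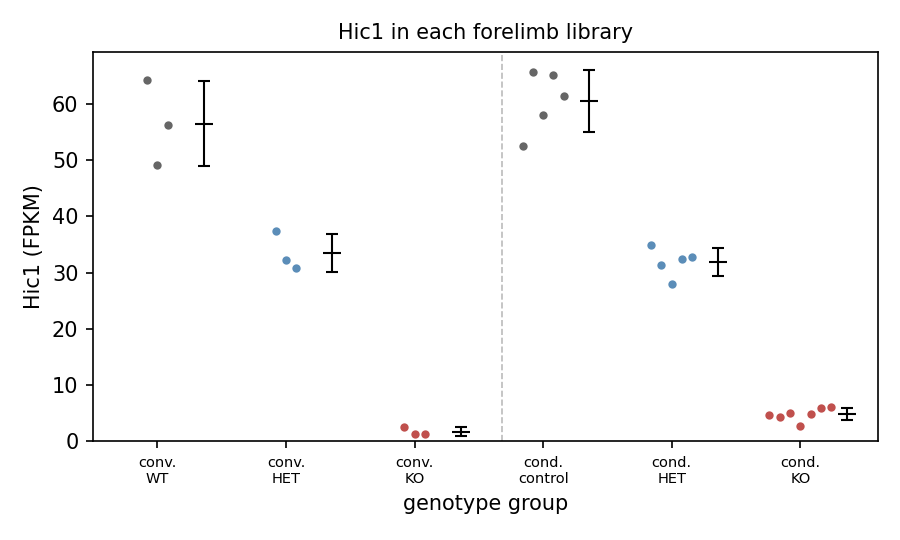
Hic1 in FPKM (vertical axis) for each of the 26 libraries, by genotype group; points are libraries, and bars beside them are the mean and SD. The knockout groups sit at 1.70 and 4.82 FPKM on average, and the heterozygotes at 33.5 and 31.9.

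The conventional knockout against wild type asks how forelimb transcripts change when Hic1 is absent from the whole embryo. Pcp4, a small calmodulin-binding protein, rose from 4.39 ± 0.419 FPKM in wild type (SD, n = 3) to between 13.2 and 13.7 in the knockout libraries (SD 0.299, n = 3), a log2 fold change of 1.43 ± 0.13 (SE, adjusted p = 0.0250), higher in 3 of 3 libraries. The processed transcript 2610507I01Rik, on chromosome 11 at 59199836 to 59202385, rose from 1.06 ± 0.0406 to 9.81 ± 3.57 FPKM (log2 fold change 2.33, adjusted p = 0.0307). Its knockout libraries were uneven, at 12.4, 11.3 and 5.74 FPKM, the last of them near the heterozygote mean of 6.27. Beside these 2 rises and the fall of Hic1, no gene passed the threshold over 12717 tested genes: 3 were called, 2 higher and 1 lower. At an unadjusted p under 0.05 there were 898 genes, 357 higher and 541 lower, where chance gives 636. The heterozygote against wild type had 47, far under that level, so 636 is no firm yardstick for this table. With a replicate block, whose use rests on the check of replicate numbers, Pcp4 and 2610507I01Rik kept their fold changes (1.43 ± 0.14 and 2.33 ± 0.22, against 1.43 ± 0.13 and 2.33 ± 0.24 without it). With 6.68 in place of 8.32 degrees of freedom both had an adjusted p of 0.0894 and Hic1 alone was called. Pcp4 lost its call when any 1 library other than knockout replicate 1 was left out (5 of 6 runs, fold change no lower than 1.39, adjusted p up to 0.200), and 2610507I01Rik lost it without any 1 wild type library or knockout replicate 2 (adjusted p up to 0.277). Leaving out wild type replicate 2 left 1 call, and leaving out knockout replicate 1 gave 5. Array weights gave 980 calls, 444 higher and 536 lower, and the length slope as a covariate gave 288, 43 higher and 245 lower, so the count depends on these settings. With the column letters as a batch term 8 genes were called, among them Slc14a2 at 1.45. Pcp4 then had an adjusted p of 0.0270 and 2610507I01Rik one of 0.0374.

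The tendon and contractile muscle lists were called lower in the conventional knockout at the preset correlation, and not with an estimated one. In none of the lists described here did a member pass the threshold over all genes tested, so the values of members are given as values and the calls are those of camera on the list. The tendon list was lower (camera adjusted p = 1.04e-04; adjusted p = 0.231 with an estimated correlation): 7 of 9 tested members had a negative fold change, and 5 were lower adjusted over the list alone. Thbs4, a thrombospondin of tendon matrix, stood at 6.12 ± 3.03 FPKM against 20.2 ± 3.25 (log2 fold change -1.64), Thbs2 at 6.87 ± 0.543 against 15.8 ± 1.71 (-1.09), and Tnmd, the tenomodulin gene, at 4.06 ± 0.769 against 12.3 ± 2.64 (-1.39). Contractile muscle genes were lower as a list (camera adjusted p = 1.05e-06; adjusted p = 0.344 with an estimated correlation), with 18 of 18 members negative and 5 lower adjusted over the list alone. The fetal myosin gene Myh8 stood at 13.7 ± 1.65 FPKM against 26.1 ± 0.684 (-0.89) and Myl1 at 75.1 ± 6.36 against 103 ± 2.93 (-0.45). Myogenic progenitor genes were not called, with a median of -0.03 and an adjusted p of 0.772.

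The lists of cartilage, of hypertrophic cartilage and bone and of extracellular matrix were called lower too, again at the preset correlation alone. Of 17 cartilage genes 14 were negative and 4 were lower adjusted over the list alone (camera adjusted p = 4.38e-04; adjusted p = 0.344 with an estimated correlation). Matn3, a cartilage matrix protein, stood at 5.39 ± 1.44 FPKM against 13.0 ± 0.717 (-1.16) and Lect1, which encodes chondromodulin, at 33.5 ± 2.61 against 69.3 ± 6.09 (-1.03). In the list of hypertrophic cartilage and bone 6 of 10 members were negative and 3 were lower adjusted over the list alone (camera adjusted p = 0.0196; adjusted p = 0.344 with an estimated correlation). Col10a1, the collagen of hypertrophic chondrocytes, stood at 0.777 ± 0.188 FPKM against 2.21 ± 0.459 (-0.85). This list lost its call with a replicate block (adjusted p = 0.0586) and with the column letters (adjusted p = 0.0748). In the extracellular matrix list 18 of 19 members were negative and 4 were lower adjusted over the list alone (camera adjusted p = 1.30e-06; adjusted p = 0.311 with an estimated correlation). Dcn, the proteoglycan decorin, stood at 27.8 ± 12.5 FPKM against 71.0 ± 7.39 (-1.43) and Col12a1 at 48.4 ± 4.44 against 74.2 ± 3.67 (-0.61).

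The neuron, mural and epidermis lists were lower as well, while the endothelium list was not called (median 0.06, adjusted p = 0.818). The neuron list was lower (camera adjusted p = 0.00157; adjusted p = 0.231 with an estimated correlation), with 4 of 5 tested members lower adjusted over the list alone. The neurofilament genes Nefm and Nefl had log2 fold changes of -0.79 and -0.70. Of 7 mural and smooth muscle genes 5 were negative and 4 were lower adjusted over the list alone (camera adjusted p = 0.0398; adjusted p = 0.344 with an estimated correlation), with Rgs5, a pericyte marker, at -0.91. The mural call was lost with a replicate block (adjusted p = 0.0701) and with the column letters (adjusted p = 0.0748). Of 13 epidermis genes 11 were negative and 1 was lower adjusted over the list alone (camera adjusted p = 0.00926; adjusted p = 0.428 with an estimated correlation). Krt10 and Krt1, keratins of differentiating epidermis, stood at -1.11 and -1.10. Imprinted growth genes were lower as a list, with 8 of 11 negative and 0 called adjusted over the list alone (camera adjusted p = 0.0463; adjusted p = 0.344 with an estimated correlation), and Mest stood at -0.29.

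Other lists were higher in the conventional knockout. Retinoic acid genes were higher as a list, positive in 9 of 10 members with 2 higher adjusted over the list alone (camera adjusted p = 0.00127; adjusted p = 0.344 with an estimated correlation). Aldh1a2, which makes retinoic acid, stood at 86.9 ± 6.34 FPKM against 40.2 ± 1.96 (log2 fold change 1.09), and Cyp26b1, which degrades it, at 45.9 ± 7.40 against 27.6 ± 1.59 (0.70). All 3 primitive erythroid globins were higher adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.344 with an estimated correlation). The embryonic globin genes Hbb-bh1 and Hba-x stood at 1.37 and 0.92. Limb patterning factors were positive in 20 of 29 members, with 0 called adjusted over the list alone (camera adjusted p = 0.00610; adjusted p = 0.344 with an estimated correlation), and Msx1 stood at 0.60. Hypoxia and glycolysis genes were positive in 10 of 12 members, with 0 called adjusted over the list alone (camera adjusted p = 0.00225; adjusted p = 0.391 with an estimated correlation). Ribosomal protein genes were positive in 69 of 78 members, with 0 called adjusted over the list alone (camera adjusted p = 2.24e-04; adjusted p = 0.648 with an estimated correlation).

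In all, 14 of the 34 lists were called in the conventional knockout, 5 higher and 9 lower, and 12 with the column letters as a batch term. Without knockout replicate 1, 20 lists were called and 13 of the 14 kept their call, with adjusted p between 1.25e-18 and 0.0300, while ribosomal proteins reversed (adjusted p = 0.909). The 20 lists not called had adjusted p from 0.0687 to 0.818: joint interzone, irregular connective tissue, mesenchymal progenitors, HIC1 targets, p53 targets, proliferation, BMP and TGF-beta, Wnt, Hedgehog, FGF, Notch, endothelium, definitive erythroid, macrophage, Schwann and neural crest, immediate early, interferon, developmental timing, genes near Hic1 and myogenic progenitors. In 5 of these 20, and in 0 of the 14 called, the median, the mean and the test differed in sign. Among members of uncalled lists, Fgf8, the growth factor of the apical ridge, stood at 2.87 ± 0.101 FPKM against 1.07 ± 0.282 (log2 fold change 0.91), and Cxcl12 was at -0.43. With an estimated correlation 0 of the 34 lists were called.

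**Figure D2:**
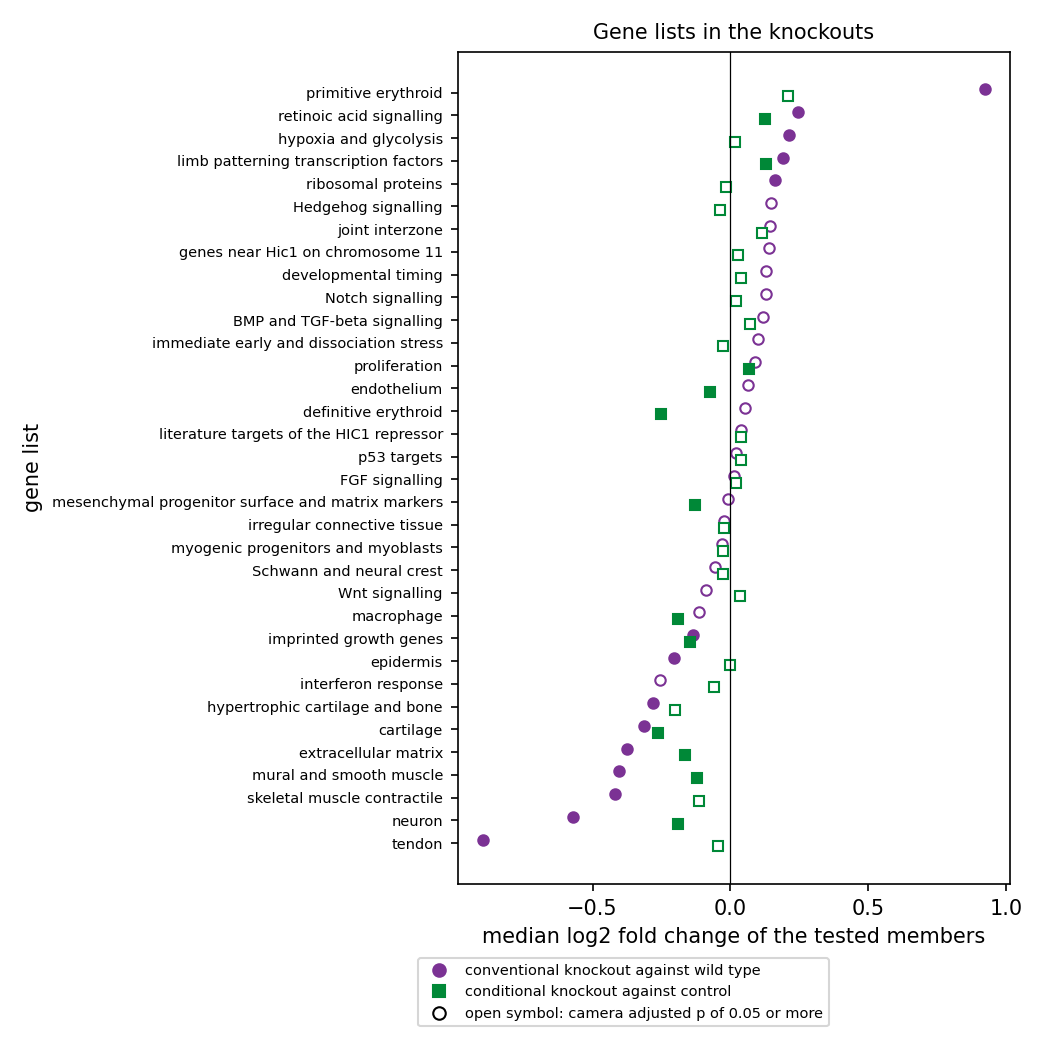
Median log2 fold change of the tested members of each of the 34 lists (horizontal axis) in the conventional knockout against wild type (circles) and the conditional knockout against control (squares); filled symbols are lists with a camera adjusted p under 0.05. The tendon list has the lowest conventional median (-0.90) and the primitive erythroid list the highest (0.92), and 0 lists are called with an estimated correlation.

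The conventional heterozygote against wild type asks whether loss of 1 allele is enough to change other genes. The 5 genes with the smallest p are given as values. 2610507I01Rik stood at 6.27 ± 0.159 FPKM (n = 3) against 1.06 ± 0.0406 (n = 3), a log2 fold change of 1.82. Gm15772, a predicted gene, stood at 492 ± 42.4 against 200 ± 7.50 FPKM (1.29), Pcp4 at 7.41 ± 1.33 against 4.39 ± 0.419 (0.63), and Rps15a-ps6, a ribosomal protein pseudogene, at 3.94 ± 0.753 against 2.26 ± 0.331 (0.59). Hic1 stood at -0.74 and was itself not called, though it was at 59.2% of wild type and lower in 3 of 3 libraries. The lack of calls here therefore does not show that loss of 1 allele leaves other genes unchanged. limma called 0 genes, with 47 at an unadjusted p under 0.05 where chance gives 636, and 1 or 2 were called with the 2 groups alone, array weights, the length slope or without wild type replicate 1 or 3. A count so far under chance means that these p-values may be too large. The spread behind them takes in knockout replicate 1 and has no replicate block, and whether these lower the count was not tested. The adjusted p of 2610507I01Rik was 0.598. The extracellular matrix list was lower, with 18 of 19 members negative at a median of -0.11 and 0 called adjusted over the list alone (camera adjusted p = 6.17e-04; adjusted p = 0.651 with an estimated correlation). The interferon list, of which 3 members were tested, was lower (camera adjusted p = 0.0149; adjusted p = 0.517 with an estimated correlation). The other 32 lists had adjusted p from 0.0761 to 0.937.

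The conventional knockout against heterozygote asks what the loss of the remaining allele adds. Hic1 fell by 3.71 ± 0.20 on the log2 scale (adjusted p = 5.27e-04), lower in 3 of 3 knockout libraries, and was the 1 gene called, with 583 at an unadjusted p under 0.05. Calls were 36 with array weights, 9 with the length slope and 2 without knockout replicate 2. Of the 34 lists 13 were called, 6 higher and 7 lower, with adjusted p between 0.193 and 0.634 once the correlation was estimated. Tendon (median -0.83), cartilage (-0.34), contractile muscle (-0.34), extracellular matrix (-0.28), hypertrophic cartilage and bone (-0.29), neuron (-0.31) and epidermis (-0.27) were lower. Hypoxia and glycolysis (0.22), retinoic acid (0.22), primitive erythroid (0.70), limb patterning (0.11), ribosomal proteins (0.17) and proliferation (0.04) were higher, and for proliferation the mean of the members was -0.00, against the sign of the test. Without knockout replicate 1, 18 lists were called, 6 higher and 12 lower, and 11 of the 13 kept their call. Retinoic acid (median 0.05, adjusted p = 0.130) and ribosomal proteins (median -0.01, adjusted p = 0.656) lost it.

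The conditional knockout against control asks for the changes when Hic1 is removed in the limb mesenchyme. The knockouts also differ from the controls in Cre and in the number of floxed alleles. This comparison cannot tell these apart from the loss of Hic1. Sst, the peptide hormone somatostatin, rose from 2.75 ± 1.46 FPKM (SD, n = 5) to 9.81 ± 1.76 (n = 7), a log2 fold change of 1.60 ± 0.19 (SE, adjusted p = 2.98e-04). Slc14a2, a urea transporter, rose from 1.42 ± 0.676 to 5.39 ± 0.592 FPKM (1.44, adjusted p = 1.93e-04). Pcp4 rose from 8.86 ± 1.65 to 21.7 ± 6.60 FPKM (1.17, adjusted p = 0.00158). Fam196b rose from 1.89 ± 0.313 to 4.13 ± 0.388 FPKM (0.83, adjusted p = 1.06e-04), Lrrc75b from 1.01 ± 0.211 to 2.81 ± 0.828 (0.90), and C1qtnf7, a secreted protein of the C1q and TNF-related family, from 3.48 ± 0.599 to 7.03 ± 1.46 (0.83). Sned1, an extracellular matrix protein, rose by 0.71, Gem, a small GTPase, by 0.55, and Gfra4, a receptor subunit of the GDNF family, by 0.54. AA465934, a processed transcript on chromosome 11, rose from 67.4 ± 6.10 to 139 ± 19.2 FPKM (1.02, adjusted p = 4.75e-06).

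Frzb, a secreted Wnt antagonist, fell in the conditional knockout from 6.44 ± 1.14 to 3.32 ± 0.334 FPKM (log2 fold change -0.77, adjusted p = 3.10e-04). Egfl6, a matrix protein with EGF repeats, fell from 36.1 ± 3.83 to 22.8 ± 3.70 FPKM (-0.65, adjusted p = 0.0215), and Mfap5, a microfibril protein, from 3.54 ± 2.06 to 0.631 ± 0.202 (-1.34, adjusted p = 0.0390). The homeobox gene Meox1 fell from 12.1 ± 1.58 to 6.83 ± 1.22 FPKM (-0.75), and Qprt, an enzyme of NAD synthesis, from 2.11 ± 0.851 to 0.527 ± 0.169 (adjusted p = 0.00711). Uchl1, a ubiquitin hydrolase abundant in neurons, fell from 43.4 ± 2.83 to 28.0 ± 2.25 FPKM (-0.62, adjusted p = 3.09e-04), the neurofilament gene Nefm from 3.57 ± 0.336 to 2.03 ± 0.318 (-0.60, adjusted p = 0.0154), and Rit2, a neuronal GTPase, from 2.63 ± 0.510 to 0.977 ± 0.517 (-0.91). Slfn9, on chromosome 11, fell by 0.68, and Kcnip4, a partner of potassium channels, by 0.49. Each of these 10 fell in 7 of 7 knockout libraries against the control mean, as each of the 10 above rose in 7 of 7.

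Over 12918 tested genes 34 were called, 19 higher and 15 lower, with 802 at an unadjusted p under 0.05 where chance gives 646. Within the letters NZ (2 knockout, 2 control) and within OB (5 knockout, 1 control) all 34 kept their direction. That decides little, since the genes were called on these same libraries, which largely fixes their sign within each part. Within NZ and OB Sst stood at 2.07 and 1.75, Slc14a2 at 1.47 and 0.93, Pcp4 at 0.88 and 1.10, Frzb at -0.83 and -0.89 and Mfap5 at -1.46 and -0.10. With the letters as a batch term 9 of the 19 and 5 of the 15 were still called, among them Sst, Slc14a2, AA465934, Fam196b, Lrrc75b, Sned1, Frzb, Slfn9, Uchl1 and Nefm, and 20 were not. Of these 20 the fold change was smaller with the letters in 13 and larger in 7, the SE was larger in 19, and the degrees of freedom went from 17.6 to 14.7. That fit also sets aside the 2 OC controls, so a lost call does not by itself point to a batch. The fold change before and after was 1.17 ± 0.16 and 0.97 ± 0.20 for Pcp4 (adjusted p = 0.0788 after), 0.83 ± 0.12 and 0.75 ± 0.16 for C1qtnf7 (0.0788), 0.55 ± 0.10 and 0.54 ± 0.14 for Gem (0.198), 0.54 ± 0.09 and 0.50 ± 0.12 for Gfra4 (0.173), and 0.45 ± 0.09 and 0.48 ± 0.11 for Ngfr (0.137). It was -0.65 ± 0.12 and -0.51 ± 0.13 for Egfl6 (0.167), -1.34 ± 0.27 and -0.81 ± 0.25 for Mfap5 (0.387), -0.75 ± 0.12 and -0.80 ± 0.16 for Meox1 (0.0671), -0.997 ± 0.160 and -0.878 ± 0.169 for Qprt (0.0532), -0.91 ± 0.17 and -0.99 ± 0.22 for Rit2 (0.127), and -0.49 ± 0.10 and -0.44 ± 0.12 for Kcnip4 (0.254). In all 25 genes were called with the letters, 20 higher and 5 lower, 128 with array weights, 52 higher and 76 lower, and 17 at a mean of at least 5 FPKM. Leaving out control replicate 1 gave 20 calls and control replicate 2 gave 17. Over 22 or 23 alternatives per gene, single libraries left out among them, the call was lost in 15 for Mfap5 and Kcnip4, 12 for Ngfr, 10 for Gem, 7 for Rit2, 6 for Egfl6, 4 for Gfra4 and Nefm, 3 for Sned1, 2 for C1qtnf7 and Meox1, and 1 for Pcp4 and Qprt.

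**Figure D3:**
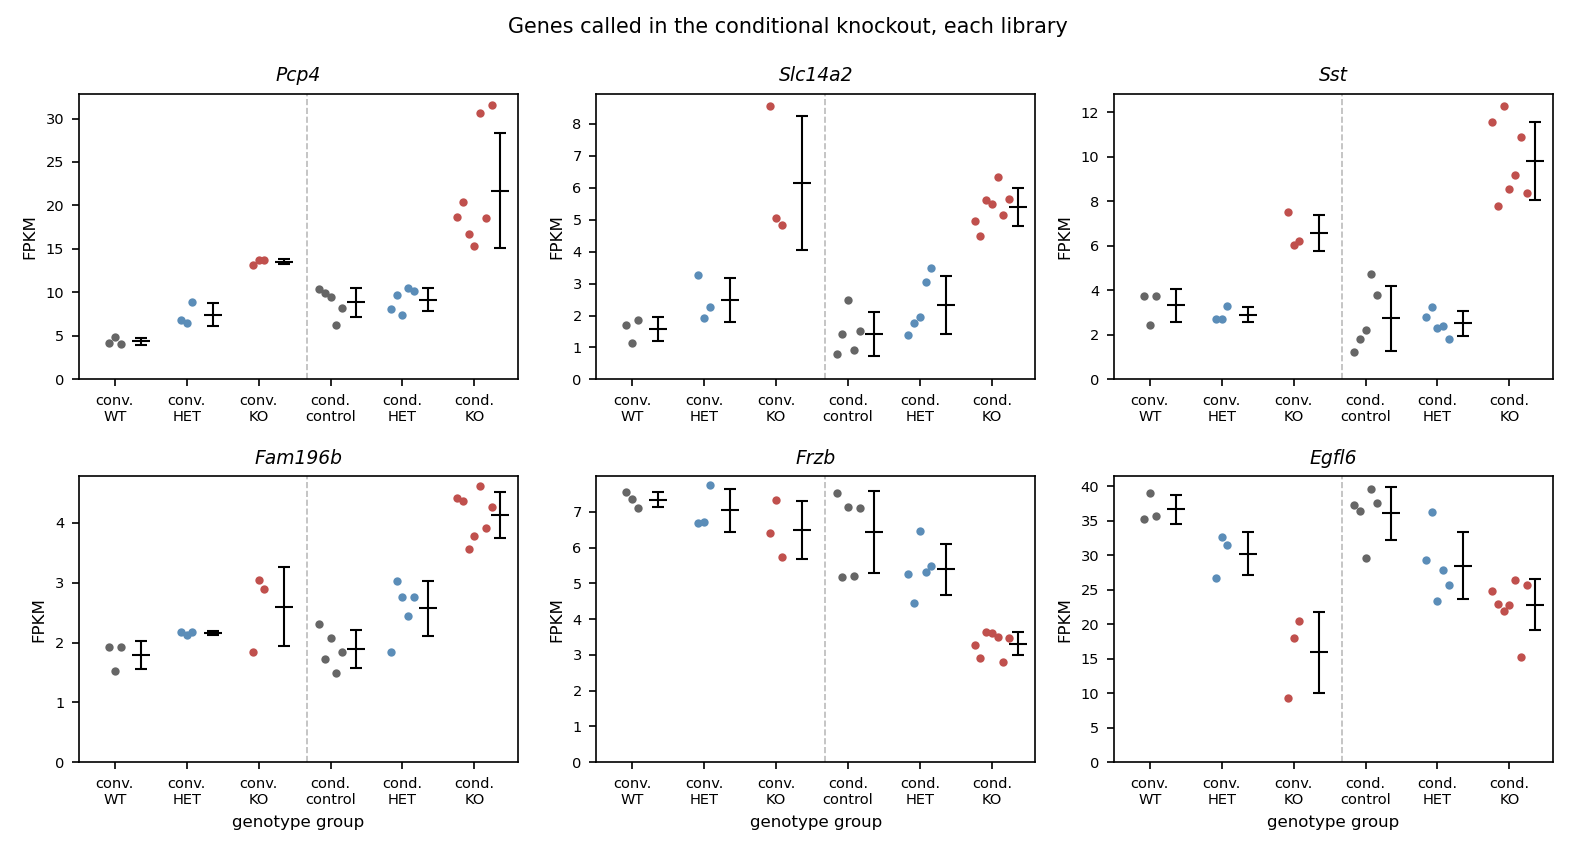
FPKM (vertical axis) of 6 genes called in the conditional knockout, for each library of the 6 genotype groups; points are libraries, and bars beside them are the mean and SD. Pcp4 averages 21.7 FPKM in the conditional knockout against 8.86 in its control, and its conventional knockout libraries lie between 13.2 and 13.7 against a wild type mean of 4.39.

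Of the 34 lists 12 were called in the conditional knockout, 3 higher and 9 lower, and most calls were lost with the column letters as a batch term. Called lists numbered 8 with the letters, 6 with a replicate block and 6 with the length slope. The neuron list was lower (median -0.19, camera adjusted p = 0.00195; adjusted p = 0.153 with an estimated correlation) and was the 1 of 12 called lists that kept its call with the letters as a batch term (adjusted p = 0.00545), with medians of -0.30 within NZ and -0.11 within OB. Nefm was the 1 member called over all genes and the 1 lower adjusted over the list alone. Retinoic acid genes were higher (median 0.13, camera adjusted p = 0.0236; adjusted p = 0.306 with an estimated correlation), with medians of 0.14 and 0.15 within NZ and OB and an adjusted p of 0.0819 with the letters. Imprinted growth genes were lower as a list, negative in 11 of 11 members with 1 lower adjusted over the list alone (median -0.15, camera adjusted p = 3.24e-06; adjusted p = 0.516 with an estimated correlation), with medians of -0.09 and -0.06 within the letters and an adjusted p of 0.215. Mesenchymal progenitor markers were lower (median -0.13, camera adjusted p = 0.0470; adjusted p = 0.516 with an estimated correlation), with Mfap5 the 1 member called, medians of -0.06 and -0.01 within the letters and an adjusted p of 0.425.

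For the remaining 8 called lists the direction of the camera test turned with the letters as a batch term, at adjusted p from 0.0833 to 0.950. Cartilage was lower with 17 of 17 members negative (median -0.26, camera adjusted p = 6.76e-04; adjusted p = 0.613 with an estimated correlation), but its medians were 0.17 within NZ and 0.12 within OB. Macrophage genes were lower (median -0.19, camera adjusted p = 1.99e-04; adjusted p = 0.516 with an estimated correlation), with medians of -0.06 and 0.20. Extracellular matrix was lower (median -0.16, camera adjusted p = 0.00165; adjusted p = 0.737 with an estimated correlation), with medians of 0.01 and 0.15. Mural genes (median -0.12, camera adjusted p = 0.0422; adjusted p = 0.516 with an estimated correlation) had medians of -0.03 and 0.08. Endothelium (median -0.08, camera adjusted p = 0.0470; adjusted p = 0.737 with an estimated correlation) had medians of -0.00 and 0.06. Definitive erythroid genes (median -0.25, camera adjusted p = 0.0470; adjusted p = 0.516 with an estimated correlation) had medians of 0.02 and 0.30. Limb patterning factors were higher (median 0.13, camera adjusted p = 0.0422; adjusted p = 0.737 with an estimated correlation), with medians of 0.10 and -0.09, and 0.01 with the letters. Proliferation genes were higher as a list, positive in 15 of 15 members with 0 called adjusted over the list alone (median 0.07, camera adjusted p = 0.0422; adjusted p = 0.737 with an estimated correlation), with medians of -0.01 and -0.08.

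The 22 lists not called in the conditional knockout had adjusted p from 0.116 to 0.906, among them tendon (median -0.04), contractile muscle (-0.11), hypertrophic cartilage and bone (-0.20), primitive erythroid (0.21), epidermis (-0.00) and ribosomal proteins (-0.02). With the letters as a batch term 7 of the 22 were called: contractile muscle (0.20, adjusted p = 0.0467), hypertrophic cartilage and bone (0.34, 0.00545), epidermis (0.22, 0.00765) and ribosomal proteins (0.05, 0.0467) in the turned direction, higher, developmental timing turned to lower (-0.14, 0.00765), and Notch (0.07, 0.0467) and Schwann and neural crest genes (0.12, 0.0313) higher. The literature targets of HIC1 were not called (median 0.04, adjusted p = 0.126), and 1 of 9 tested members, Ccnd1, which encodes cyclin D1, was higher adjusted over the list alone, at 96.2 ± 6.96 FPKM against 79.1 ± 6.81 (log2 fold change 0.28, adjusted p = 0.0675 over all genes). Irregular connective tissue genes were not called as a list, with 2 members higher and 2 lower adjusted over the list alone. Ngfr, the low-affinity neurotrophin receptor, was the called member of the Schwann and neural crest list, at 34.4 ± 4.39 against 24.9 ± 3.02 FPKM (0.45, adjusted p = 0.0374), a call lost in 12 of 23 alternatives. In 2 of the 22 lists the median, mean and test differed in sign. The sex-linked list held 0 called transcripts in all 6 comparisons, but the mix of libraries with high and low Xist differed between conventional groups. Xist stood at 101, 195 and 0.0442 FPKM in the wild type libraries, 108, 0.104 and 0.152 in the heterozygotes and 0.0129, 164 and 202 in the knockouts.

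Of the 33 calls other than Hic1, 6 lie on chromosome 11. Smg6, a nuclease of nonsense-mediated decay whose gene at 74925823 to 75164448 ends next to Hic1, rose from 14.8 ± 1.32 to 21.2 ± 1.84 FPKM in the conditional knockout (log2 fold change 0.49, adjusted p = 9.85e-04). AA465934, at 83291699 to 83294632, and Slfn9, at 82978390 to 82991830, lie on the other side. Hic1 aside, 3 of 420 tested genes within 20 Mb of Hic1 were called, against 30 of 12410 elsewhere (one-sided Fisher exact p = 0.0923). The called gene Ngfr lies 20.4 Mb from Hic1, just outside this window, so the counts and the p depend on its edge. In the list of 25 tested genes near Hic1, 2 were higher adjusted over the list alone, and the list was not called (adjusted p = 0.116). 2610507I01Rik was not raised in the conditional knockout, where its highest library was 1.45 FPKM.

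**Figure D4:**
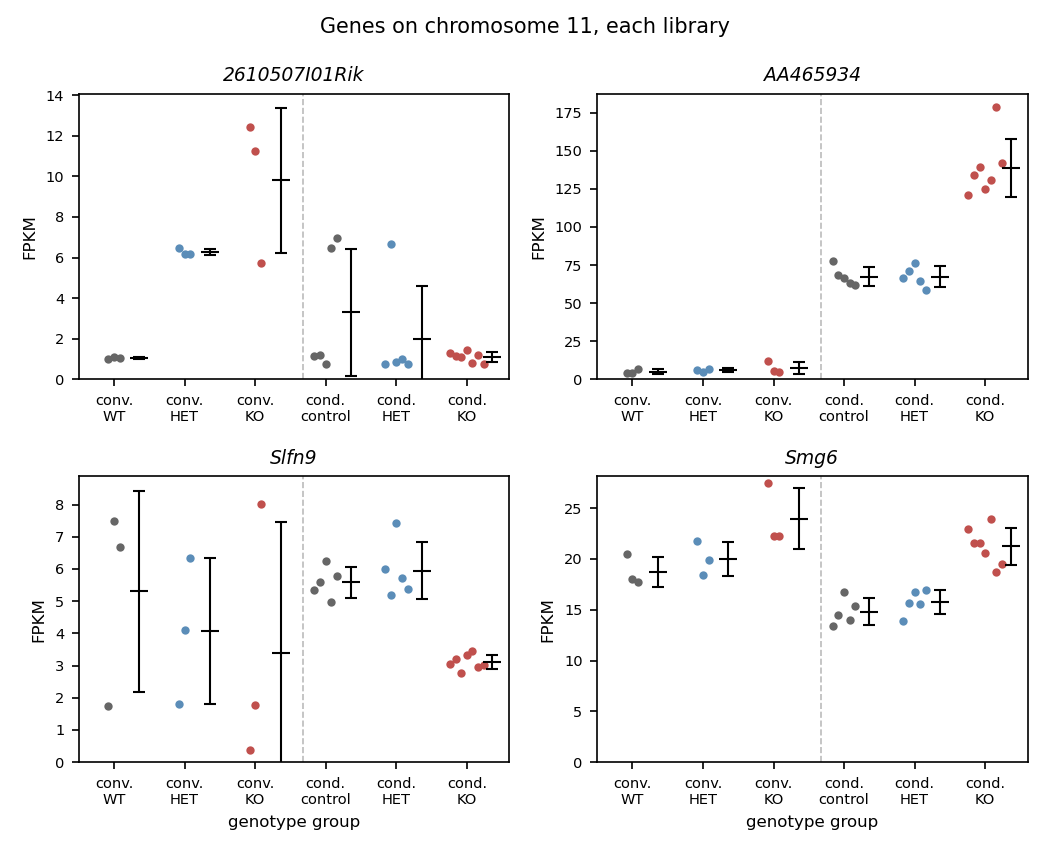
FPKM (vertical axis) of 4 genes on chromosome 11 for each library of the 6 genotype groups; points are libraries, and bars beside them are the mean and SD. AA465934 averages 67.4 FPKM in the conditional control and 5.08 in the conventional wild type, and 2610507I01Rik averages 9.81 in the conventional knockout and 6.27 in its heterozygote.

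The conditional heterozygote against control asks for the effect of losing 1 allele in the limb mesenchyme. The heterozygotes carry Cre and the controls do not, so an effect of Cre cannot be told apart from it. Hic1 fell by 0.90 ± 0.13 on the log2 scale (adjusted p = 0.0209), lower in 5 of 5 libraries, and was the 1 gene called, with 725 at an unadjusted p under 0.05. That call was lost with the column letters as a batch term, at -0.85 ± 0.18, where the spread is wider, and in 8 of the 10 runs with 1 library left out (from -0.95 to -0.86, adjusted p up to 0.123), all but those without control replicate 1 or heterozygote replicate 1. Macrophage genes were negative in 11 of 11 members (median -0.27, camera adjusted p = 1.14e-05; adjusted p = 0.593 with an estimated correlation). Ribosomal proteins were negative in 70 of 78 (median -0.12, camera adjusted p = 5.43e-06; adjusted p = 0.627 with an estimated correlation), and FGF pathway genes were positive in 11 of 11 (median 0.12, camera adjusted p = 0.00508; adjusted p = 0.593 with an estimated correlation). In all 12 lists were called, 3 higher and 9 lower, with adjusted p from 0.593 to 0.627 once the correlation was estimated, and with the letters 3 were called, 1 of them shared. Of the 33 genes other than Hic1 called in the knockout, 30 had the same sign in the heterozygote (90.9%), with a median ratio of heterozygote to knockout effect of 0.376. The 2 comparisons share their controls, and both set Cre against no Cre, so an effect of Cre would give like signs too. So would a batch that follows the letters, since OB marks 5 knockout and 3 heterozygous libraries but 1 control, and OC 2 controls. Among 100 simulations of an unchanged heterozygote the share was 69.7% in the median and 90.9% at most, with a ratio of at most 0.221. They drew each gene independently and carried no batches, so their range may be too narrow for the real libraries and does not exclude chance. In 10 splits of the controls between the 2 comparisons the share was 75% in the median and the ratio 0.193. The share ran from 66.7% to 87.0% there, over a median of 14.5 called genes. The simulation was changed to the 33 smallest p per run after a first version, which called more genes, had been seen.

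The conditional knockout against heterozygote compares 2 groups that both carry Cre. They still differ in the number of floxed alleles, which this comparison cannot tell apart from the loss of Hic1. Sst rose from 2.52 ± 0.552 to 9.81 ± 1.76 FPKM (log2 fold change 1.62, adjusted p = 3.79e-04), Pcp4 from 9.15 ± 1.32 to 21.7 ± 6.60 (1.12, adjusted p = 0.00616), AA465934 by 1.02, Slc14a2 by 0.98 and C1qtnf7 by 0.67. Slfn9 fell by 0.75 and Frzb from 5.40 ± 0.719 to 3.32 ± 0.334 FPKM (-0.56, adjusted p = 0.0208). Each moved the same way in 7 of 7 knockout libraries. The call was lost in 16 of 23 alternatives for C1qtnf7 (adjusted p up to 0.434), 10 of 22 for Slc14a2 (up to 0.0865) and 8 of 22 for Frzb (up to 0.0804), and in 0 for Sst, Pcp4, AA465934 and Slfn9. Hic1 fell by 2.52 ± 0.12 (adjusted p = 6.84e-10). In all 10 genes were called, 7 higher and 3 lower, with 598 at an unadjusted p under 0.05; leaving out heterozygote replicate 1 gave 5, heterozygote replicate 4, knockout replicate 2 or knockout replicate 7 gave 6, and knockout replicate 4 gave 16. Calls were 29 with array weights, 6 with quantile normalisation and 5 at a mean of at least 5 FPKM. Ribosomal proteins were the 1 list called, higher, with 73 of 78 members positive (median 0.11, camera adjusted p = 3.46e-06; adjusted p = 0.838 with an estimated correlation), and the other 33 had adjusted p from 0.0665 to 0.992. Called lists numbered 4 with a replicate block, 8 with the letters and 3 with the length slope, ribosomal proteins among them each time.

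Between the strategies, Pcp4 was called higher and Hic1 lower in both knockouts. The conditional call of Pcp4 was lost with the column letters as a batch term (0.97, limma adjusted p = 0.0788). Chance gives an overlap of 0.00303 genes higher (one-sided Fisher exact p = 0.00302). Hic1 is the targeted gene, so its overlap follows from the design. With a replicate block the overlap was 1 gene, Hic1, as it was without any 1 conventional wild type library or conventional knockout replicate 2 or 3; with the length slope it was 10. Genes called in the conditional knockout were also looked up as lists in the conventional one, in a test chosen after the data were seen. Of 19 risen genes 18 had a positive conventional fold change and 3 were higher adjusted over the list alone (camera p = 0.00426 with an estimated correlation). Of 11 fallen genes other than Hic1 that were tested, 9 were negative and 4 were lower adjusted over the list alone (camera p = 0.00737 with an estimated correlation). Without conventional knockout replicate 1, 17 of the 19 were positive and 7 higher (camera p = 0.0166 with an estimated correlation), and 10 of the 11 were negative and 6 lower (p = 0.00261). In the conventional knockout Slc14a2 stood at 1.45, Sst at 0.82, Egfl6 at -1.22, Nefm at -0.79, Rit2 at -0.74, Meox1 at -0.50 and Frzb at -0.16. Over the 12557 genes tested in both, the fold changes correlated with a Pearson r of 0.210 and a Spearman rho of 0.186 across genes, which are not independent replicates, and with the column letters in both fits r was -0.0307. It was 0.364 without conventional knockout replicate 1, 0.131 without conventional knockout replicate 3, 0.123 without conditional knockout replicate 4 and -0.155 with the conditional heterozygote in place of the control. The test of the difference between the strategies called 0 genes with limma's moderated standard errors, with 303 at an unadjusted p under 0.05.

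**Figure D5:**
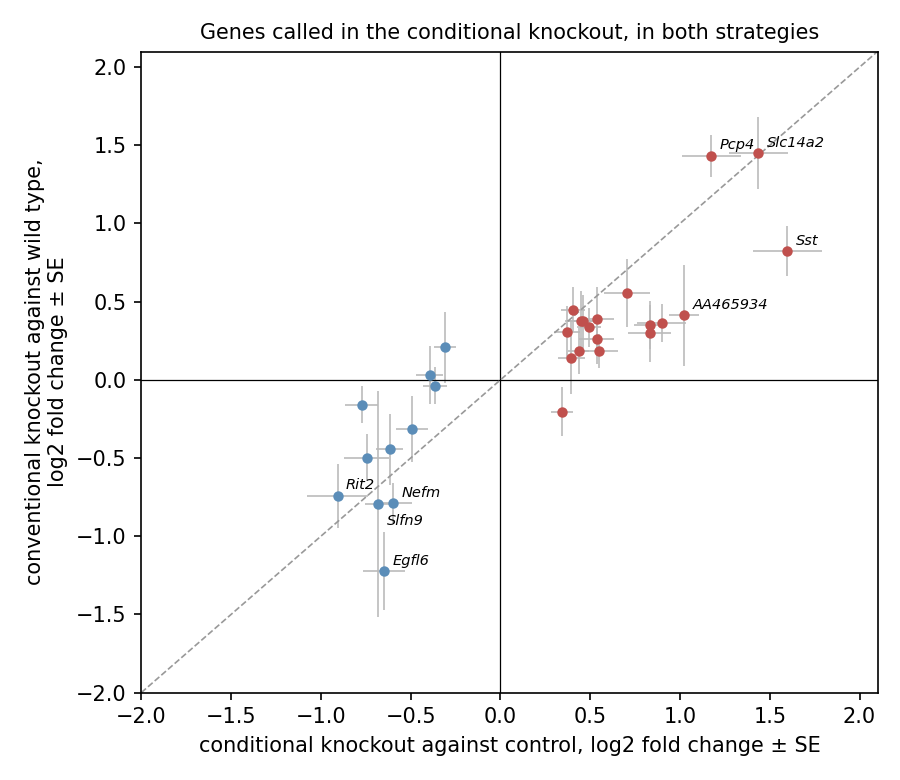
Log2 fold change of genes called in the conditional knockout (horizontal axis) against their log2 fold change in the conventional knockout (vertical axis), with SE bars and the line of equality; Hic1 is left out. Of the 19 genes that rose 18 lie above 0 on the vertical axis, and of the 11 that fell 9 lie below 0.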

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

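The 3 tests of the genes near Hic1 in this part were chosen only after the result was seen; the comparison of each library with the rest of its group was set in advance. Among 37 genes picked for possible naming, not all of which are named, 111 groups of 5 or 7 conditional libraries were searched for a highest or lowest library that lies far from its group, and 6 groups (5.41%) held one, where chance gives about 1 in 20. AA465934 stood at 179 FPKM in conditional knockout replicate 6, with the other knockout libraries between 121 and 142. Egfl6 stood at 15.3 FPKM in the same library, with the others between 22.0 and 26.4. Gfra4 stood at 8.13 FPKM in conditional heterozygote replicate 4, with the others between 6.35 and 6.86. Nefm stood at 4.45 FPKM in conditional heterozygote replicate 2, the 1 library with the letters OA, with the others between 2.42 and 2.78. Ccnd1 stood at 90.9 FPKM in conditional control replicate 3, the 1 control with the letters OB, with the others between 74.2 and 78.3. Rspo3 stood at 11.2 FPKM in conditional heterozygote replicate 1, with the others between 12.8 and 13.4.

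AA465934 and Slfn9, called in the conditional knockout within 20 Mb of Hic1, did not lie nearer the knockout in the heterozygote than in the control, which both carry 1 floxed allele: the larger of their ratios of heterozygote to knockout effect was -0.00118, against a median of 0.387 over 30 called genes elsewhere. Smg6, the other called gene in that window, had a ratio of 0.179, and 6 of the 30 elsewhere also had ratios under 0.25. Alleles of another mouse strain carried along with the targeted locus may account for these values. An effect that needs the loss of Hic1 on both chromosomes would give them too. The conventional knockout also lacks Hic1 on both, and AA465934 stood there at 7.47 ± 4.00 FPKM against 5.08 ± 1.57 in wild type. Without knockout replicate 1, at 12.1 FPKM, its log2 fold change there was 0.05 ± 0.22 (SE), against 1.02 in the conditional knockout. The conventional wild type level of AA465934 is far below the 67.4 ± 6.10 FPKM of the conditional control. The conventional values therefore do not tell whether the higher conditional level rises with the loss of Hic1 on both chromosomes, and such an effect stays open. Slfn9 ran from 0.373 to 8.03 FPKM in the conventional knockout, so for it such an effect stays open too. That called genes lie near Hic1 no more often than other genes was not excluded (one-sided Fisher exact p = 0.0923). This depends on the edge of the window, as Ngfr, also called, lies just outside it at 20.4 Mb. For 2610507I01Rik the tables argue against loss of Hic1 as the cause, since its highest conditional knockout library was 1.45 FPKM while the median of the conventional heterozygote libraries was 6.18. The conditional controls with the letters OC stood at 6.49 and 6.97 FPKM for this gene and the OA heterozygote at 6.67, with every other conditional library at 1.45 or lower. Its level thus moved apart from the Hic1 genotype there. Whether it follows an allele on chromosome 11 was not tested.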

How the results depend on the processing

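The fits with the column letters, the fits with a length slope, the list tests without conventional knockout replicate 1 and the gene-by-gene array weights in the conventional fits were chosen only after the data were seen. The fall of Hic1 in both knockouts kept its direction and its call under every alternative run. Over their alternatives the 22 genes named as called in the conditional knockout against control kept their direction in 495 runs and their call in 413, and 9 never lost it: AA465934, Fam196b, Frzb, Lrrc75b, Slc14a2, Slfn9, Smg6, Sst and Uchl1. The 7 named against the heterozygote kept direction in 158 runs and their call in 124. Pcp4 and 2610507I01Rik in the conventional knockout kept direction in 34 runs and their call in 19. The 45 uncalled genes picked for possible naming in the conventional knockout, not all of which are named, kept direction in 751 of 752 runs, Frzb turning to 0.01 with quantile normalisation, and passed the threshold in 68. Depth is unknown, so the limit it sets cannot be given; genes under a mean of 5 FPKM have no value under that filter.

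Calls in the conventional knockout against wild type were 1 without a low-value filter, 5 with quantile normalisation, 1 with a replicate block, 1 with the 2 groups alone, 980 with array weights, 8 with the column letters and 288 with the length slope. In the conventional heterozygote against wild type calls were 2 with the 2 groups alone, 1 with array weights and 2 with the length slope, under which Hic1 was called at -0.75 and 7 lists were called. In the conventional knockout against heterozygote calls were 36 with array weights and 9 with the length slope. In the conditional knockout against control calls were 17 at a mean of 5 FPKM, where fewer genes are tested, and 128 with array weights, and called lists were 6 with a replicate block and 6 with the length slope. In the conditional heterozygote against control calls were 0 with a pseudocount of 0.1 (Hic1 at -0.92), with no filter (-0.90), with a replicate block (-0.90) and with the letters (-0.85), and 3 lists were called with the letters; at an unadjusted p under 0.05 limma gave 725 genes as reported. In the conditional knockout against heterozygote calls were 5 at a mean of 5 FPKM, 6 with quantile normalisation and 29 with array weights, and called lists were 4 with a replicate block, 8 with the letters and 3 with the length slope. With an estimated correlation 0 lists were called in each of the 6 comparisons. Genes called in both strategies numbered 1 without a filter, 1 with a replicate block and 10 with the length slope. The correlation between strategies was 0.168 with a replicate block, 0.304 with the length slope, -0.0307 with the letters and -0.155 with the conditional knockout set against the heterozygote. Except where fewer genes or samples enter, the cause was not tested.

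With the letters, the direction of the camera test reversed for these lists in the conditional knockout against control, at adjusted p of 0.0467 (contractile muscle), 0.231 (cartilage), 0.00545 (hypertrophic cartilage and bone), 0.674 (limb patterning), 0.0833 (extracellular matrix), 0.0833 (proliferation), 0.654 (endothelium), 0.950 (mural), 0.947 (definitive erythroid), 0.397 (macrophage), 0.00765 (epidermis), 0.00765 (developmental timing) and 0.0467 (ribosomal proteins). In the conditional heterozygote muscle (0.435), extracellular matrix (0.676) and imprinted genes (0.571) reversed. Without conventional knockout replicate 1 ribosomal proteins reversed in the conventional knockout (0.909). The cause was not tested.

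Leaving out 1 library gave 1 to 5 calls in the conventional knockout against wild type (1 without wild type replicate 2, 5 without knockout replicate 1) and 20 lists without knockout replicate 1. It gave 0 to 1 in the conventional heterozygote against wild type (1 without wild type replicate 1 or 3), with Hic1 from -0.83 to -0.64, and 1 to 2 in the conventional knockout against heterozygote (2 without knockout replicate 2), with 18 lists without knockout replicate 1. It gave 17 to 46 in the conditional knockout against control (20 without control replicate 1, 17 without control replicate 2). It gave 0 to 1 in the conditional heterozygote against control, with Hic1 from -0.95 to -0.86 (adjusted p 0.0305 to 0.123) and called without control replicate 1 or heterozygote replicate 1. It gave 5 to 16 in the conditional knockout against heterozygote (5 without heterozygote replicate 1, 6 without heterozygote replicate 4, knockout replicate 2 or knockout replicate 7, 16 without knockout replicate 4). Shared genes ran from 1 to 2 (1 without any 1 of the conventional wild type libraries or conventional knockout replicate 2 or 3), genes that differ between strategies from 0 to 1 (1 without conventional knockout replicate 3), and the correlation from 0.123 (without conditional knockout replicate 4) to 0.364 (without conventional knockout replicate 1).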

Other observations

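The tests of why conventional knockout replicate 1 stands apart, of the column letters as a cause of list calls and of a younger stage were chosen only after the result was seen; the splits of the libraries were set in advance. The test within the letters NZ was chosen after the effect of the letters on the lists was seen, with its bounds written before its own value was. Among conditional libraries, the tendon gene Thbs4 stood at 8.33 ± 3.56 FPKM in the knockout against 18.4 ± 3.67 in the control, a log2 fold change of -1.13 with an adjusted p of 0.280 that did not pass. Ebf2, a transcription factor of connective tissue, stood at 11.7 ± 1.22 against 14.3 ± 0.899 FPKM (-0.27), and Rspo3, a secreted activator of Wnt signalling, at 11.1 ± 1.49 against 14.1 ± 2.07 (-0.31), neither called. The macrophage gene Mrc1 stood at -0.38 and the keratin gene Krt18 at -0.26, and Tlcd2, which lies near Hic1, at 0.39, none of them called.

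The conditional heterozygote held further lists that camera called against control, each with an adjusted p from 0.593 to 0.627 once the correlation was estimated. Adjusted over the list alone, 1 member of the definitive erythroid list was lower and 0 members of the others passed, so the counts that follow are of signs. Proliferation genes were positive in 15 of 15 members (median 0.10, adjusted p = 2.15e-04) and limb patterning factors in 24 of 29 (0.16, adjusted p = 0.00633). Contractile muscle was negative in 18 of 18 members (-0.20, adjusted p = 0.00707), extracellular matrix in 18 of 19 (-0.20, adjusted p = 0.00508), endothelium in 11 of 11 (-0.10, adjusted p = 0.00508), interferon genes in 4 of 4 (-0.31, adjusted p = 0.00508), definitive erythroid genes in 6 of 7 (-0.35, adjusted p = 0.00633), epidermis in 12 of 13 (-0.18, adjusted p = 0.0185) and imprinted genes in 10 of 11 (-0.13, adjusted p = 0.0185). Xist ran from 0.0129 to 202 FPKM between conventional libraries.

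Conventional knockout replicate 1 had a median correlation of 0.869 with the other libraries of its table. These correlations do not decide on a library batch of the letters CH. The 2 other CH libraries, at 0.971 and 0.970, lay below every CL library, the lowest of which had 0.978, as such a batch would give. They also lay far above this library, so a batch of the same strength in all CH libraries would not give its place. Loss of Hic1 is argued against. The steepest length slope among the other knockout libraries of both strategies was -0.0625, against -0.294 here. Its deviations fell with transcript length (Spearman rho of -0.371 across genes, with -0.180 the lowest of the other conventional libraries), so loss of long transcripts in that library may account for its place. The trend with length also follows the letters: with this library left out of the means, the 2 other CH libraries had a rho of -0.260 and -0.307, and the lowest of the CL libraries had -0.0997. A batch that lowers long transcripts in the CH libraries may thus account for part of it, and the letters CH go with replicate 1 of each genotype. What led to such a loss, and whether this embryo also differs in stage, was not tested.

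The lists called in the 2 knockouts were weighed against library batches and stage. In the conditional knockout 1 of 12 called lists kept its call with the library batches given by the column letters as a term. That fit also sets aside the 2 OC controls. Batches or the smaller set of controls may thus account for much of the rest, and the fit cannot tell these apart. Within the letters NZ 8 of the 12 had a median in the reported direction, which lies between the bounds written for it and leaves the part of batches open. In the conventional knockout 2 of 2 lists whose genes fall with embryonic age, primitive erythroid and developmental timing, were called higher without knockout replicate 1 (adjusted p of 0.00205 and 0.00118). With all libraries the timing list was not called (adjusted p = 0.440; primitive erythroid 0.00116), and with an estimated correlation neither was, with that library (0.344 for primitive erythroid, 0.648 for timing) or without it (0.227 and 0.159). On the calls at the preset correlation alone, a younger stage of the conventional knockout embryos may account for the lower tendon, muscle, cartilage and epidermis lists. A delay of development that follows from the loss of Hic1 would give the same values and stays open as untested.

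Other splits of the same libraries were set against each result. With 10 splits of 3 against 3 a share under 0.05 cannot be reached. For genes called, 1 of 10 splits gave as many as the conventional knockout against wild type (3, highest other 1), 10 of 10 as many as the heterozygote against wild type (0, highest other 2) and 2 of 10 as many as the knockout against heterozygote (1, highest other 2). For lists called these numbers were 1 (14, highest other 11), 9 (2, highest other 15) and 2 (13, highest other 15). Among the 4 splits of each comparison that part all replicate pairs as the real one does, the highest others were 0 genes and 11 lists, 0 genes and 10 lists, and 0 genes and 15 lists; the remaining splits put same-numbered libraries on 1 side.

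In the conditional series 100 splits were used. For the 34 genes of the knockout against control 1 of 100 splits, the real one, was as large, with a highest other of 1. For the 10 genes of the knockout against heterozygote it was again 1 of 100, with a highest other of 2. The splits ignored the letters, and a split that mixes genotypes adds any real difference to the spread. They therefore do not exclude a grouping that follows the letters. For the 2 genes called in both strategies (1 of 100, highest other 0) the splits decide nothing, since no other split called more than 1 gene and Hic1 is 1 of the 2. For the 0 genes that differ between strategies (100 of 100, highest other 2) they decide nothing either, since every split reaches 0. Chance was not excluded for the 12 lists of the knockout against control (15 of 100, highest other 19), the 1 gene and the 12 lists of the heterozygote against control (5 of 100, highest other 1702, and 36 of 100, highest other 22) or the 1 list of the knockout against heterozygote (98 of 100, highest other 20). The splits of heterozygote and control with 1702, 1295 and 903 calls put the 4 OB libraries on 1 side with 1 library of other letters (NZ, OC and OA in turn), which points to a structure of the samples that follows the letters; with the letters as a term the heterozygote comparison called 0 genes.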
